A study of Rattus norvegicus with 30 samples.

How the data were processed

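RNA from brain tissue of 30 rat pups was sequenced after library preparation with a stranded total RNA kit, per the labels. The labels give strain and exposure for each pup. They give no age, sex, litter, brain region, dose or sequencing batch. Groups were taken from the labels: NEC control (n = 8), NEC VPA (n = 7), GAERS control (n = 8) and GAERS VPA (n = 7). Replicate numbers follow the order of deposit and pair nothing. Pups may share dams, so p-values measure only the spread between these samples, and if litters were exposed as a whole, differences between litters would count as differences of exposure.

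The values the authors deposited are raw counts per Ensembl gene, whole numbers with no normalization. FastQC and STAR 2.5 with the rat build Rnor_6.0 (rn6) are named per the submitters' processing notes. The counting tool, annotation release and use of strand are not given in the sources used here, so genes that overlap, lie antisense to each other or have near-identical copies may share reads. A table of 47357 RefSeq gene rows of another assembly, GRCr8, was at hand for names, but its Ensembl column is empty in every row, so none of the 32586 identifiers could be matched. For this reason 39 gene lists fixed before the data were examined, and covariates for sex and for blood, were not run. No row lacked an identifier. The rule for named genes was fixed at the same time as the lists: genes highest and lowest by log2 fold change among those with adjusted p under 0.05 and a mean log2 CPM of at least 2, with the same sign in both strains for VPA. Its condition on gene symbols had to be dropped, and it was shortened to 2 identifiers per direction for each of the VPA average and strain in controls.

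Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups (minimum count 10, minimum total count 15), which left 15885, and 8413 of the rest were at 0 in all libraries. Library sizes were scaled by TMM, which assumes that most genes do not change or change evenly in both directions. A single quasi-likelihood fit with robust dispersion and 4 group means on all 30 libraries gave 6 comparisons: VPA averaged over strains, VPA in NEC, VPA in GAERS, the interaction, strain in controls and strain in exposed pups. P-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic. CPM were computed with TMM-scaled library sizes. The agreement of the 2 strains was measured by correlation across genes and overlap of calls.

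Replicate libraries of a group differed by more than counting noise, with a lowest chi-square per degree of freedom of 5.36 among pairs, so no library was counted as a repeat of another. Depth was 26963266 to 56568656 counts per library. The fit was tested on simulated data with 200 changed genes. For the VPA average, 62% of 1.25-fold and 96% of 2-fold changes were recovered, and 2.84% of calls were false. For VPA in NEC it recovered 28% and 94%, with 3.21% false, and for VPA in GAERS 54% and 92%, with 6.36% false. For strain in controls it recovered 42% and 98%. Each comparison had a single simulation with its own random draw of 50 genes per fold. The gap between 28% and 54% therefore does not show a difference in power between NEC and GAERS. Simulated noise was independent between genes, so the false shares do not cover variation shared across genes.

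Alternatives fixed before the data were examined, for the gene counts and named genes, were RLE and upper-quartile scaling, no filter and a filter of 1 CPM in 7 libraries, a size threshold of 0.5 on the log2 scale, DESeq2 1.42.0, limma 3.58.1 (voom with quality weights, and trend for the interaction), covariates for library number and log2 total count, surrogate variables from sva 3.50.0, fits on the compared groups alone or with an additive model, and leaving out each library. For the correlation between strains, only a cut at a mean log2 CPM of at least 2 was fixed beforehand. Chosen after the data were examined were the correlation under the other alternatives, a covariate from 8 genes that divide the pups of each group, a covariate from the first component of the residuals, leaving out the 3 libraries farthest out on the first principal component, permuted exposure labels under the surrogate variable and residual models, the per-pup index, the tests of components and of the share of counts in the 100 most abundant genes, the depth test without each library, standard errors from fits of each strain alone, the division by expression level, and a second draw of random splits. No paired analysis was possible because the labels give no numbers or litters that pair pups.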

Results

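Bulk RNA sequencing was performed on brain tissue of 30 rat pups from 2 inbred strains. GAERS (Genetic Absence Epilepsy Rats from Strasbourg) develop spontaneous absence seizures, and NEC (Non-Epileptic Controls) are their seizure-free inbred counterpart. Pups of each strain were either exposed to valproate (VPA), an antiseizure drug that also inhibits histone deacetylases, or left as controls. There were 8 NEC control, 7 NEC VPA, 8 GAERS control and 7 GAERS VPA libraries. Total counts ranged from 26963266 to 56568656 per library. They averaged 36356544 ± 8436942 (SD, n = 8) in NEC controls, 33116636 ± 3934688 (SD, n = 7) in exposed NEC, 36332926 ± 3768405 (SD, n = 8) in GAERS controls and 32023025 ± 2574967 (SD, n = 7) in exposed GAERS. Exposed libraries were on average shallower than control libraries, with 32569830 ± 3244632 counts (SD, n = 14) against 36344735 ± 6312328 (SD, n = 16), with a p of 0.0395 by a two-sided permutation test within strain (100000 resamples). That p depended on single libraries: it was 0.05 or more in 15 of the 30 tests that left out 1 library, and without NEC control 7, the deepest, the difference shrank from -3774905 to -2331183 counts (permutation p = 0.0712). Of 32586 genes, 15885 had enough counts to be tested, and these held 99.96% to 99.98% of the counts of each library. Genes carried only rat Ensembl identifiers. The files used here do not pair these with symbols, so genes are described by number, size, direction and expression level, and few are named by identifier.

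Strain separated the brains, and exposure shifted group means with overlap between pups. The second principal component of log2 CPM (counts scaled to a common library size), with 20.6% of the variance, separated GAERS from NEC in controls (exact two-sided permutation test, p = 0.000155, adjusted p = 0.000932 over the 6 component tests made) and in exposed pups (exact p = 0.000583, adjusted p = 0.00175). The third component, with 8.60% of the variance, shifted with VPA by 14.9 units in NEC (exact p = 0.00668, adjusted p = 0.010) and by 18.8 units in GAERS (exact p = 0.00466, adjusted p = 0.00932). It also followed the 2 sets of pups given by the 8 genes described below, which these tests ignored. NEC controls lay at -18.4 to -13.9 in one set and -4.03 to -2.68 in the other. Within each set, every exposed pup lay above every control of its strain. The first component, with 20.7% of the variance, spread pups within groups, with an SD of 12.7 to 21.1 units. It differed between exposed and control pups by 24.7 units in NEC (exact p = 0.0255, adjusted p = 0.0306) and by 2.04 units in GAERS (exact p = 0.818), where the difference was within the spread between pups. The NEC difference on the first component includes NEC control 3 at -49.9 and NEC VPA 7 at 49.8, the lowest and highest scores of all pups. The other NEC controls lay at -12.0 to 24.0 and the other exposed NEC pups at -6.35 to 29.3. The difference was not tested without those extreme pups, nor was it tested whether it differed between strains. These 6 tests were chosen after the components had been plotted.

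**Figure D1:**
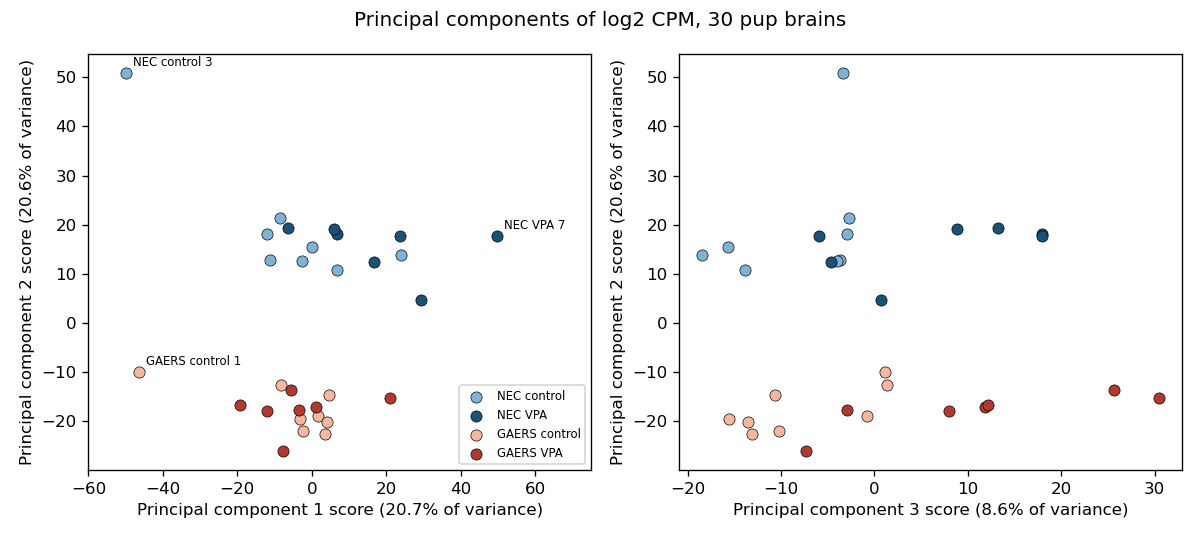
Scores of the 30 pup brains on principal components 1 and 2 (left) and 3 and 2 (right) of log2 CPM, in arbitrary units, 1 point per pup, colored by group. NEC and GAERS pups lie apart on component 2, group means on component 3 are -8.08 in NEC controls and 6.86 in exposed NEC, and -7.66 in GAERS controls and 11.1 in exposed GAERS, with overlap between pups, and NEC control 3, NEC VPA 7 and GAERS control 1 lie farthest out on component 1.

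The main question was what VPA exposure changed in the brain, averaged over both strains. VPA shifted a large part of the transcriptome by small amounts: 4620 of 15885 genes (29.1%) differed. Of these, 2205 were higher and 2415 lower in exposed pups. The share higher was 47.7%, but 56.5% with upper-quartile scaling and 50.6% without NEC control 3. The median size among the 4620 genes was 0.20 on the log2 scale, or 1.15-fold. Changes over 0.5 on the log2 scale were found in 302 genes (153 higher, 149 lower), and changes over 1 in 35 genes (24 higher, 11 lower). Most of these 35 had a mean log2 CPM under 2 or differed in sign between strains. Among the remaining called genes the second highest log2 fold change was 0.999 and the second lowest -0.767. Calls used edgeR's quasi-likelihood test with a Benjamini-Hochberg adjusted p under 0.05, here and below.

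The highest of the well-expressed genes was ENSRNOG00000029286, which rose from a low level. It was at 1.01 ± 0.427 CPM (SD, n = 8) in NEC controls and 18.8 ± 10.4 CPM (SD, n = 7) in exposed NEC pups, and at 1.23 ± 1.07 CPM (SD, n = 8) in GAERS controls and 13.6 ± 18.4 CPM (SD, n = 7) in exposed GAERS pups. Its log2 fold change was 3.85 ± 0.42 (SE; 14.4-fold, edgeR adjusted p = 6.74e-07). One pup, GAERS VPA 4, was at 54.8 CPM against 3.60 to 11.4 CPM in the other 6 of its group, and without it the log2 fold change was 3.35. ENSRNOG00000038616 doubled with much less spread between pups, from 12.2 ± 3.27 to 23.1 ± 2.40 CPM in NEC (SD, n = 8 and 7) and from 10.7 ± 0.897 to 22.7 ± 3.21 CPM in GAERS (SD, n = 8 and 7). Its log2 fold change of 1.0 ± 0.08 (SE) had the smallest adjusted p of the comparison, 1.41e-09 by edgeR.

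The lowest 2 well-expressed genes fell in exposed pups. ENSRNOG00000006237 went from 10.5 ± 2.51 to 4.56 ± 1.5 CPM in NEC (SD, n = 8 and 7) and from 10.5 ± 2.74 to 6.01 ± 2.19 CPM in GAERS (SD, n = 8 and 7), a log2 fold change of -1.0 ± 0.15 (SE, edgeR adjusted p = 3.40e-05). ENSRNOG00000016043, the more abundant of the pair, went from 98.7 ± 31.0 to 49.3 ± 18.6 CPM in NEC (SD, n = 8 and 7), and its log2 fold change over both strains was -0.77 ± 0.17 (SE, edgeR adjusted p = 0.00117). In GAERS alone it was at 83.6 ± 24.2 CPM in controls and 57.7 ± 16.5 CPM in exposed pups (SD, n = 8 and 7), which did not pass the test (log2 fold change -0.53 ± 0.23 SE, edgeR adjusted p = 0.218). For both genes the highest controls were the outlying NEC control 3 and GAERS control 1, and exposed and control pups overlapped in each strain. The log2 fold change of ENSRNOG00000016043 over both strains was -0.69 without NEC control 3. Across 13 alternative analyses it ran from -0.77 to -0.57.

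**Figure D2:**
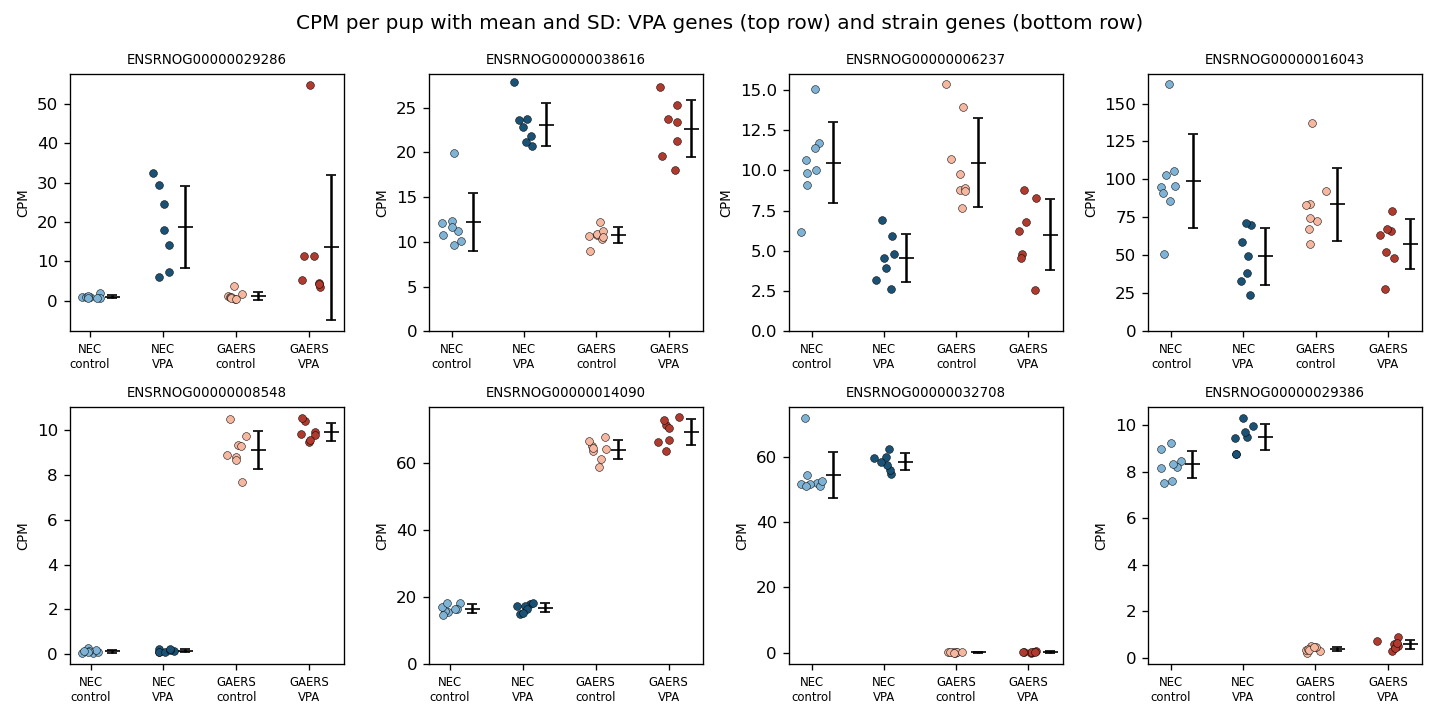
CPM of each pup (points) with the mean and SD of each group (black bars) for the 4 genes named for VPA (top row) and the 4 named for strain in controls (bottom row), on linear axes. ENSRNOG00000038616 lies at 18.1 CPM or more in each exposed pup, and 1 control, NEC control 3 at 19.97 CPM, overlaps that range.

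Called genes of high abundance were mostly lower in exposed pups. The share of genes called rose with expression, from 10.9% of the 1882 genes with a mean log2 CPM below 0 to 44.4% of the 720 genes at 8 and above, while the median standard error fell from 0.18 to 0.04. Of the 320 called genes at 8 and above, 242 (75.6%) were lower in exposed pups, and with upper-quartile scaling the share was 66.4%. Between 2 and 4, 510 of 901 called genes were higher. A like tilt was seen for strain in controls. There 29 of 35 called genes at 8 and above were lower in GAERS, and 173 of 292 between 2 and 4 were higher. That comparison uses the same control libraries as the VPA average, so the tilts are not independent. In NEC control 3 the 100 most abundant genes held 17.3% of counts, against 15.1% to 15.6% in the other NEC controls. The tilt was not examined without this library. The cause of the tilt was not tested. The division by expression level was made after the data were examined.

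Within NEC, VPA changed 3913 genes, 1760 higher and 2153 lower (2207 higher and 1930 lower with upper-quartile scaling). The median size was 0.29 on the log2 scale (1.22-fold), and 684 genes passed 0.5, of which 420 were lower. No single library decided this count, which ranged from 2989 to 4493 when each was left out in turn. The balance of directions did depend on NEC control 3. Without it 2114 genes were higher and 2081 lower, and 3354 of the 3913 were kept.

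Within GAERS, VPA changed 607 genes, 299 higher and 308 lower (49.3% higher, or 58.5% with upper-quartile scaling), with a median size of 0.29 (1.22-fold). Of these, 128 passed 0.5, and 85 of the 128 were higher. Among the 720 genes with a mean log2 CPM of 8 and above, 47 were called and 44 of them were lower. The 100 most abundant genes of each library also held a smaller share of its counts in exposed GAERS, 14.7% ± 0.298 (SD, n = 7) against 15.2% ± 0.170 (SD, n = 8) in controls (exact two-sided permutation test, p = 0.00186, adjusted p = 0.00373 over the 2 strains), with 6 of 7 exposed pups below all controls. In NEC the share was 15.2% ± 0.475 (SD, n = 7) against 15.6% ± 0.699 (SD, n = 8), exact p = 0.305. These tests were chosen after the data were examined. The number of genes called in GAERS depended on single pups and on the model. It was 279 without GAERS VPA 4, 337 without GAERS VPA 5, 354 without GAERS control 5 and 1034 without NEC control 3. NEC control 3 is not one of the pups compared and acts only through the fit shared by all libraries. The count was 3756 with 5 surrogate variables in the model, which kept all 607 genes. A fit on the GAERS pups alone called 525 genes and kept 424 of the 607.

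Whether the strains responded differently was tested as an interaction. No gene passed the edgeR test: 0 of 15885 had an adjusted p under 0.05, the smallest was 0.303, and 1278 had an unadjusted p under 0.05 where 794 would be expected by chance. DESeq2 called 2 genes, limma-trend 0, edgeR with surrogate variables 1, limma-voom with sample quality weights 156, and edgeR with the first component of the residuals as a covariate 775, a model for which 1 of 19 permuted labelings gave more (up to 1797). The larger count of VPA genes in NEC was thus not shown to be a difference between the strains. In simulated data the interaction test recovered 20% of 1.25-fold, 62% of 1.5-fold and 82% of 2-fold differences, so small differences would often be missed. These rates come from a single draw of 50 genes per fold, with noise independent between genes. They may differ in the real data.

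**Figure D3:**
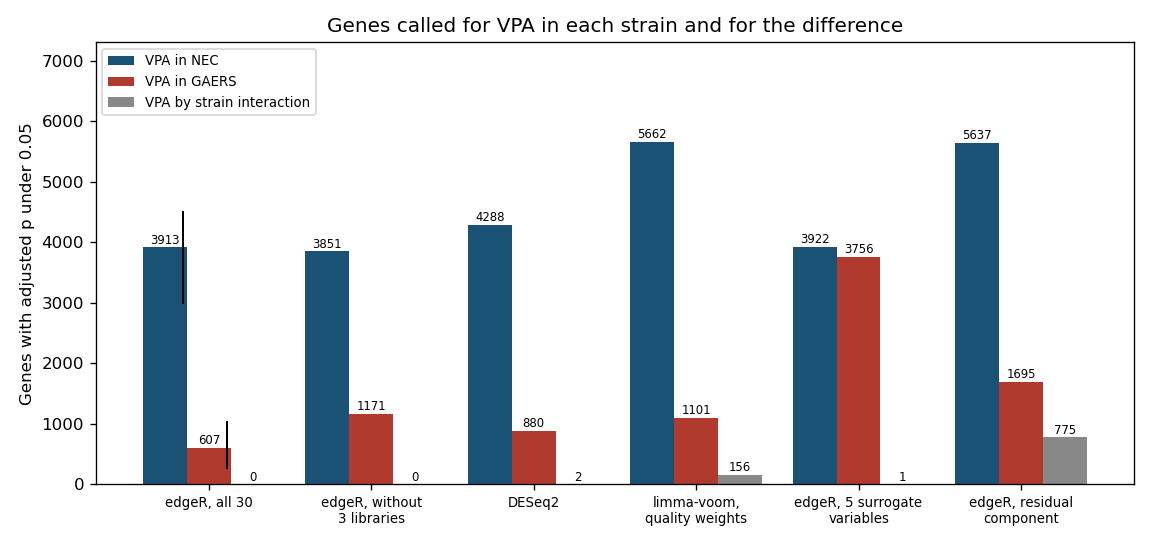
Number of genes with adjusted p under 0.05 for VPA in NEC, VPA in GAERS and the interaction, under 6 models (bars, from 0), with the range over the 30 fits that each left out 1 library as black lines for the first model. The NEC count exceeds the GAERS count 3913 to 607 with all 30 libraries, and the counts are 3922 and 3756 with 5 surrogate variables.

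The direction of the VPA response was mostly the same in the 2 strains among called genes, and less so among all genes. Over all 15885 tested genes, 72.1% had the same sign in NEC and GAERS. Of the 4620 genes called for the average, 4599 had the same sign in NEC and GAERS, although calling on the average itself favors such genes. Among genes called in NEC, 3652 of 3913 (93.3%) had the same sign in GAERS, and among those called in GAERS, 590 of 607 (97.2%) had the same sign in NEC. The calls overlapped in 196 higher genes (33.1 for independent lists) and 227 lower genes (41.7 for independent lists), with 0 genes called in opposite directions. The 2 comparisons share no library. The figure for independent lists takes genes as independent, which they are not. No permuted reference was made for the overlap or the shares of sign.

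Across all tested genes, which are not independent replicates, the log2 fold changes of the strains correlated with a Pearson r of 0.436 and a Spearman rho of 0.530. Leaving out each library in turn, a check added for r after the data were examined, gave 0.285 to 0.50. On the 11995 genes with a mean log2 CPM of at least 2, the correlation of differences between group means was 0.522. This did not exceed chance when exposure labels were permuted within strain (one-sided permutation p = 0.08, permuted r from -0.833 to 0.700). The covariance of 0.0173 exceeded every permuted value (highest 0.0170, one-sided permutation p = 0.01, the smallest that 100 labelings can give).

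A per-pup index was chosen after the data were examined: the mean log2 CPM of genes called higher minus that of genes called lower in the other strain. With NEC-called genes, exposed and control GAERS pups differed by 0.31 on the log2 scale (exact two-sided permutation test, p = 0.00435, n = 7 and 8), with 5 of 7 exposed pups above all 8 controls. Without GAERS control 1, the lowest pup, the difference was 0.24 (exact p = 0.00874, n = 7 and 7). GAERS-called genes separated NEC pups by 0.63 (exact p = 0.000155, n = 7 and 8), with 7 of 7 exposed pups above all controls.

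**Figure D4:**
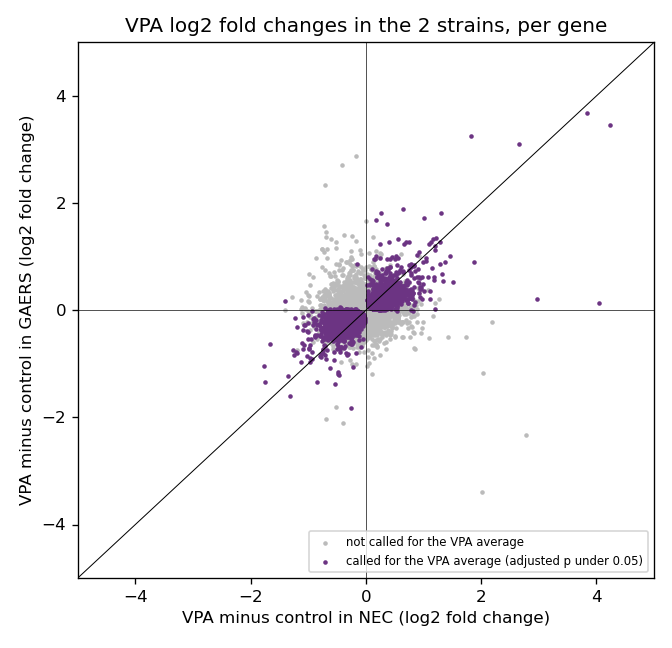
VPA log2 fold change of each of the 15885 tested genes in NEC (horizontal) and GAERS (vertical), with the line of equality; purple points are the 4620 genes called for the VPA average. Of the purple points, 4599 lie in the upper right or lower left quadrant.

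Strain differences in unexposed pups included more changes over 1 on the log2 scale than the VPA average did, in fewer called genes. Between GAERS and NEC controls 1375 genes differed, 641 higher and 734 lower in GAERS. The share higher was 46.6%, but 57.3% with upper-quartile scaling and 53.1% without NEC control 3. The median size of the called genes was 0.37 on the log2 scale (1.29-fold), 515 passed 0.5, 220 passed 1 and 57 passed 2. The count was 3000 with limma-voom quality weights and 2801 with the residual component as a covariate. The VPA average, taken over both strains, had a median standard error of 0.060 against 0.082 here, so the counts differ in power. Within single strains VPA passed 1 in 66 genes in NEC and 36 in GAERS. It passed 0.5 in 684 genes in NEC, more than strain did, and in 128 in GAERS. Called genes numbered 3913 for VPA in NEC but only 607 in GAERS.

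Of the 4 genes named for strain, 3 were close to absent in 1 strain. ENSRNOG00000032708 was at 54.5 ± 7.06 CPM in NEC controls and 0.170 ± 0.108 CPM in GAERS controls (SD, n = 8 each), a log2 fold change of -8.31 ± 0.21 (SE, edgeR adjusted p = 7.25e-24). ENSRNOG00000029386 was at 8.30 ± 0.585 and 0.385 ± 0.0982 CPM (SD, n = 8 each), a log2 fold change of -4.42 ± 0.13 (SE, edgeR adjusted p = 8.57e-22). In the other direction, ENSRNOG00000008548 was at 0.139 ± 0.0647 CPM in NEC and 9.12 ± 0.832 CPM in GAERS controls (SD, n = 8 each), a log2 fold change of 6.04 ± 0.15 (SE, edgeR adjusted p = 6.28e-24). ENSRNOG00000014090 was present in both, at 16.7 ± 1.24 and 64.1 ± 2.81 CPM (SD, n = 8 each), and was 3.85-fold higher in GAERS (edgeR adjusted p = 7.25e-24).

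Exposed pups showed the strain differences again. Between exposed GAERS and exposed NEC pups 1951 genes differed, 950 higher and 1001 lower in GAERS (48.7% higher, or 58.8% with upper-quartile scaling), and 1281 differed without GAERS VPA 2. Of the genes called in controls, 826 were also called in exposed pups (169 for independent lists), and 0 were called in opposite directions. The log2 fold changes correlated across genes with r = 0.742 (Spearman rho 0.428), and no library was shared. No permuted reference was made for this overlap or correlation. The 4 genes named for strain held in exposed pups, with log2 fold changes of 5.97 for ENSRNOG00000008548, 2.04 for ENSRNOG00000014090, -7.89 for ENSRNOG00000032708 and -3.99 for ENSRNOG00000029386. The count was 3697 with the residual component as a covariate.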

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

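The test of the depth of NEC control 3 and the check of its strain label were chosen after its position had been seen. Within each group, 68 sets of values were searched for a pup far from the rest, and 21 were found. Chance would give about 3.4 if the values of each set were normally distributed. The sets include skewed CPM of genes chosen from these data, and they reuse the same pups and related measures. The 21 is therefore no measured excess over chance.

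In 4 libraries the correlation with the group was low. The median correlation with the rest of the group was 0.976 for NEC control 3 (others 0.989 to 0.993), 0.985 for NEC VPA 7 (others 0.990 to 0.992), 0.982 for GAERS control 1 (others 0.991 to 0.993) and 0.984 for GAERS VPA 4 (others 0.989 to 0.991). NEC control 3 also had a TMM factor of 0.905, 17.3% of counts in its 100 most abundant genes (others 15.1% to 15.6%), a second component score of 50.9 (others 10.7 to 21.4), ENSRNOG00000038616 at 19.97 CPM and ENSRNOG00000032708 at 71.8 CPM. GAERS control 1 had a first component score of -46.3 (others -8.24 to 4.64), ENSRNOG00000016043 at 137.3 CPM, and an index of -0.48 from genes called in NEC. GAERS VPA 4 had ENSRNOG00000029286 at 54.8 CPM.

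NEC control 3 was the farthest from its group, with 369 genes over 2-fold above and 960 over 2-fold below the group median, and the biological coefficient of variation of NEC controls was 0.158 with it and 0.0939 without it. Its depth of 35293830 counts lay within the range of its group, and on a scale from 0 (other NEC controls) to 1 (exposed NEC) it lay at -0.17. These values argue against low depth and against a wrong exposure label. All 25 genes that separate the strains completely followed NEC in it. They were chosen with this library included, so that outcome was fixed and does not test its strain label. Its departure correlated with that of GAERS control 1 at 0.527, below the 95th percentile in size of 0.578 over 337 pairs from different groups; the bound set beforehand counted this against a shared axis, but that reading was changed to open after the value was seen, because those pairs, up to 0.688 and -0.783, themselves carry shared departures and are no reference without them. Other tissue or another brain region in the sample may also explain the 369 raised genes, and without gene names no marker could be read, so this stays open. The design gives no biological explanation to test for a single pup.

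The other values were single ones. NEC control 7 was the deepest library at 56568656 counts (others 30713506 to 37383067) and had the most genes detected, 19896. GAERS control 2 had a TMM factor of 1.02 (others 0.996 to 1.01), GAERS VPA 7 had 15.3% of counts in its 100 most abundant genes (others 14.4% to 14.7%, GAERS controls 14.98% to 15.44%), and GAERS VPA 2 had a second component score of -26.1 (others -17.9 to -13.7). ENSRNOG00000029286 was at 1.98 CPM in NEC control 2 and 3.65 CPM in GAERS control 3, and ENSRNOG00000038616 was at 27.9 CPM in NEC VPA 2.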

How the results depend on the processing

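The residual component, the covariate from 8 genes and the fits without 3 libraries were chosen after the data were examined. Each of the 8 named genes kept its direction and its adjusted p under 0.05 in all 13 alternatives and all 30 fits without 1 library. Requiring a log2 fold change over 0.5 left 302 genes for the VPA average, 684 in NEC, 128 in GAERS, 515 for strain in controls and 593 for strain in exposed pups, as a stricter threshold must. The VPA count in GAERS moved under 6 of 14 alternatives, more than any other count: besides that threshold, it was 401 without a filter on low counts, 1101 with limma-voom quality weights, 3756 with surrogate variables, 1695 with the residual component and 1171 without the 3 outlying libraries. The interaction gave 2 genes with DESeq2, 156 with limma-voom quality weights, 1 with surrogate variables and 775 with the residual component. That component is built from the residuals and so can understate the error; over 19 permuted exposure labelings it gave a median of 1 and up to 1797 interaction genes, a median of 9 and up to 1226 in NEC, a median of 0 and up to 42 in GAERS, and a median of 0 and up to 374 for the VPA average. Of those permuted counts 1 reached the real one for the interaction and 0 did for the other 3 comparisons. With surrogate variables the 19 permuted fits gave at most 1 gene. Strain in controls gave 3000 genes with limma-voom quality weights and 2801 with the residual component, and strain in exposed pups 3697 with the latter. For the correlation between strains only a cut at a mean log2 CPM of at least 2 was fixed beforehand, and it gave 0.560; the other alternatives, leaving out libraries included, were added after the data were examined. It was 0.0904 without a filter on low counts, where genes with few or no reads in most libraries enter. Apart from the residuals' construction, the threshold and the filter, the cause of these moves was not tested. Leaving out 1 library gave 3881 to 5225 genes for the VPA average, 2989 to 4493 in NEC, 279 to 1034 in GAERS, 0 to 2 for the interaction, 1115 to 1806 for strain in controls, 1281 to 2737 for strain in exposed pups, and a correlation of 0.285 to 0.50. With log2 total count as a covariate the VPA average had 3586 genes, of which 3469 were among the 4620. Not run, for lack of gene names, were the 39 gene lists and the covariates for sex and blood.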

Other observations

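Tests of precision, single libraries, surrogate variables, the residual component and the 3 outlying libraries for the strain counts, and those of group membership and sex for the 8 genes, were chosen after the results were seen. What the first draw of random splits, the size of the response and the covariate from the 8 genes would show was written before their results were seen, although the 8 genes themselves were found in these data.

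Some genes divided the pups completely. In 33 genes the 30 values fell into 2 separate sets, with thresholds set after the data were examined. In 25 of these the sets were the strains, with 9 genes higher in GAERS and 16 higher in NEC. The other 8 genes shared 1 split that ran through every group.

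Those 8 genes differed between the sets by at least 4.6 on the log2 scale, 2 being high in one set and 6 in the other. The sets held 3 and 5 NEC controls, 3 and 4 exposed NEC, 5 and 3 GAERS controls, and 3 and 4 exposed GAERS pups. The smallest share of a group was thus 3 pups, which argues against exposure as the source. Genes split by strain had been set aside in choosing the 8, so for strain this is no test. The split did not carry the VPA response, since 4859 genes were called for the VPA average with the 8-gene score as a covariate, against 4620. Sex of the pups may explain such a split, but 0 of the 8 genes had a name or position in the tables used here and the labels give no sex, so this stays open.

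More genes were called for VPA in NEC than in GAERS, 6.45 times as many. In fits of each strain alone the median standard errors had a GAERS to NEC ratio of 0.916, and the count ratio stayed at 4.06 or more without any 1 library, which argue against lower precision from depth or number of pups and against a single library. Variation between pups unrelated to the groups may account for part of the gap: the ratio was 1.04 with 5 surrogate variables. A gap remained with the residual component (5637 to 1695 genes), without the 3 outlying libraries (3851 to 1171) and with limma-voom quality weights (5662 to 1101). Under permuted exposure labels the residual component model gave up to 1226 genes in NEC and up to 42 in GAERS. How much of its gap comes from the model itself therefore cannot be told. Surrogate variables also changed the effects. The median absolute log2 fold change went from 0.137 to 0.108 in NEC and from 0.087 to 0.101 in GAERS. Their 3922 NEC genes included 3026 of the original 3913. Whether they hold only variation unrelated to the groups was not tested. A larger response in NEC stays open: the root mean square log2 fold change was 0.22 in NEC and 0.15 in GAERS (two-sided permutation of strain labels, p = 0.1), and missing the threshold excludes nothing. The interaction count of 0 to 775 across models leaves it equally undecided.

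Random splits of the same pups were drawn to see how many genes chance gives. Exposure was permuted within strain, or strain within exposure, 99 times. For the VPA average 1 of 100 splits, the real one, gave 4620 genes or more (highest other 2523, a split that kept 22 of 30 real labels, including all of NEC). For VPA in NEC 1 of 99 did (real 3913, highest other 0), for VPA in GAERS 1 of 100 (607, highest other 2), for strain in controls 1 of 100 (1375, highest other 519) and for strain in exposed pups 1 of 100 (1951, highest other 4). A random grouping of pups is thus an unlikely source of these 5 counts. It is not excluded, since 1 of 100 is the smallest share that 99 draws can give. The splits treat pups as exchangeable, and litters, which the labels do not give, could still carry part of the 3 VPA counts. For the interaction the real count was 0, which all 100 splits reach by construction, so the splits decide nothing there (highest other 0). One draw left the NEC labels as they were, gave 3654 genes and was not counted for VPA in NEC, a choice made after its count was seen; with it counted, the real split still had the most genes. A second draw that allowed no such split, also made after the first had been seen and not used for these figures, gave highest counts of 397, 0, 196, 269, 9 and 1 for the VPA average, NEC, GAERS, the interaction, strain in controls and strain in exposed pups.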
